A study of Homo sapiens with 6 samples.

How the data were processed

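Total RNA of HaCaT cells, 3 samples without and 3 with 1 µg/ml histamine for 24 h, was measured on Illumina HT-12 bead arrays, 1 array per sample. Per the labels, the cells grew in DMEM with 1.5 mM calcium and 10% serum, RNA was extracted with a Qiagen RNeasy kit and biotin-labelled cRNA was hybridized. The text on treatment is the same for all samples, so the groups were taken from the agent label, which reads control for 3 of them. The labels speak only of a triplicate, and whether the replicates are separate cultures is not given in the sources used here. The p-values therefore measure the spread between these samples, which may be technical in part. Sample names of the control group come from 1 numbered series and those of the histamine group from another, and the files give no slide position or scan date, so no batch term could be fitted.

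The deposited signal intensity values are mean bead signals per probe as GenomeStudio exports them, per the file headers, with no background subtraction and no normalization between arrays. The detection p-values, also per the file headers, give for each probe and array how its signal ranks among the negative control beads. The authors' processed value table is on a log2-like scale and quantile normalized, with a median of 7.46 on every array; its exact transform, which may be a variance-stabilizing one, is not given in the sources used here. GenomeStudio 2010.1 and lumi, without a version, are named per the submitters' processing notes. The values were computed here from the signals, and the processed table served as an alternative.

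Signals of 47322 probes were background corrected with the normexp model of limma 3.58.1 (R 4.3.3, statmod 1.5.0). The negative control distribution was inferred from the detection p-values and an offset of 16 was added. The corrected signals were quantile normalized and put on the log2 scale. The offset compresses folds of dim probes. A probe was kept with a detection p-value under 0.05 on at least 3 of 6 arrays, which left 17871 probes. Of all probes 30112 carry 1 gene symbol, 8 carry several and 17202 none. Symbols were checked by Entrez identifier against the gene table of assembly GRCh38.p14 (30073 matched, 0 updated), and no probe coordinates were used. Each gene was represented by its brightest kept probe with 1 symbol, which gave 10406 genes, 2702 of them with more than 1 kept probe; 4125 kept probes without a symbol were fitted apart.

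A linear model with the 2 groups was fitted with limma, with empirical Bayes moderation and an intensity trend (median total degrees of freedom 17.82). P-values, which are 2-sided, were adjusted by Benjamini and Hochberg over all genes tested, and a gene rose or fell at an adjusted p-value under 0.05. Differences are histamine minus control on the log2 scale with the moderated standard error. A gene below background on every array of 1 group gets only a bound, written as at least so many fold. For the bound, any value under the lowest normalized value of a detected probe on its array was raised to that value. Such genes numbered 66 in the control group (39 changed) and 99 in the histamine group (42 changed).

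The 24 gene lists were fixed before the data were examined, as were the comparison, the thresholds and the rule for named genes. They are keratinocyte lists (terminal differentiation, basal layer, stress keratins and antimicrobial peptides, tight junction and desmosome), response lists (inflammatory cytokines and NF-kB targets, type I interferon, antigen presentation, EGFR ligands and immediate early genes, hypoxia and glycolysis, unfolded protein and amino acid stress, heat shock, NRF2 targets, metallothioneins), and lists of mitosis, DNA replication, matrix and proteases, cholesterol synthesis, ribosomal proteins, respiratory chain, histamine receptors and metabolism, and fibroblast, melanocyte, immune cell and endothelial markers. Lists with at least 3 measured members were tested with camera (limma) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 19 lists. By that rule, named genes are the 10 largest increases and 10 largest decreases among genes past the threshold whose groups do not overlap, up to 4 measured members per list with the largest absolute difference, and all measured members of the histamine receptor list. List members named beyond these, the other probes of named genes, and the genes of the other observations were chosen after their values were seen. Lists for skeletal muscle, heart, erythrocytes, liver, adipocytes, tissue stroma, acute phase and complement, and YAP and TEAD targets were written after the first results were seen.

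Alternatives were no background correction (signals floored at 1), the processed value table, an offset of 50, median scaling in place of quantile normalization, no filter on dim probes, a stricter filter (detection p-value under 0.01 on 6 arrays), all kept probes tested singly, and the mean of a gene's kept probes. Others were moderation without the trend, robust moderation, array quality weights, the replicate number as a block, an adjusted p-value under 0.01, and each array left out in turn. Leaving out skeletal muscle and hemoglobin genes was an alternative chosen after seeing the data. The median scaling used the median of all 47322 probes, taken before the detection filter. Only 36.7% to 40.9% of probes were detected per array, so the median probe lay below detection. That scaling thus lines up background levels rather than expressed genes. With median scaling limma found no spread of variances beyond the trend, so each gene's variance there is that of the trend.

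The steps were tested on simulated data with 10406 genes and 3 arrays per group. Of 50 genes with a true log2 change of 0.5, 7 were called, 29 of 50 at a change of 1, 46 of 50 at 1.5 and 46 of 50 at 2. Among unchanged genes 3 were called, and 0 were called where no change was simulated. With 1 list shifted by 0.5, 1 of 19 lists was called. The simulated genes were independent of each other, so the list test was not tried on genes that vary together. Changes under 2-fold were often missed in this simulation, in which 200 of 10406 genes changed. On the real arrays 2224 genes were called, which makes the adjusted threshold less strict, so these shares need not hold there. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.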

Results

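HaCaT, an immortalized line of human skin keratinocytes, was profiled with Illumina HT-12 bead arrays after 24 h in 1 µg/ml histamine and without it. Histamine is the amine that mast cells release in skin, and the comparison asked which keratinocyte genes change with it. Each of the 2 groups held 3 arrays. The median probe signal was 122, 141 and 133 on the control arrays and 122, 121 and 124 on the histamine arrays, and 36.7% to 40.9% of the 47322 probes were detected per array. Over the 10406 genes tested, arrays of a group correlated with each other at 0.98 to 0.99 and arrays of different groups at 0.96 to 0.97; these are correlations across genes, which are not independent replicates. The first principal component held 56.4% of the variance. It placed control replicates 1, 2 and 3 at -29, -25.9 and -15.5 and histamine replicates 1, 2 and 3 at 27, 21.4 and 21.9. The median standard error of a log2 difference was 0.17, with n = 3 per group.

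S100A8 and S100A9, which encode the subunits of the antimicrobial protein calprotectin, rose 21.4-fold and 14.9-fold with histamine. Their log2 differences were 4.42 ± 0.13 and 3.90 ± 0.13 (SE; adjusted p = 2.29e-13 and 3.47e-13). SAA1, an acute phase protein, rose by 3.41 ± 0.23 on the log2 scale, and SERPINB4, a squamous cell serpin, by 3.26 ± 0.19. IL6, a proinflammatory cytokine, rose by 3.22 ± 0.20, and IL1RL1, the receptor of the cytokine IL33, by 3.22 ± 0.26. SAA1, IL6 and IL1RL1 were each detected on 1 of 3 control arrays, and the other probes of SAA1 and IL1RL1 gave 2.05 and 1.80. TMEM70, an assembly factor of the mitochondrial ATP synthase, had the largest decrease among genes measured in both groups (-3.00 ± 0.19; adjusted p = 5.99e-09), while its other kept probe gave -0.53 with an adjusted p of 0.0721. Below background on every histamine array were IGF2BP1, an RNA-binding protein, at least 3.79-fold lower, SIPA1L3, at least 3.53-fold lower, and the amino acid transporter SLC7A3, at least 2.77-fold lower. The cytokine IL16 was at least 2.05-fold lower, the probe annotated to the pseudogene OR2A20P at least 3.34-fold, and the probe annotated to MIR877 at least 2.76-fold, also below background on every histamine array. These bounds rest on group means and move with single arrays. Without control replicate 2 that of IL16 was 1.43-fold. Without control replicate 1 that of SIPA1L3 was 2.75-fold and that of OR2A20P 2.81-fold. AMY1B fell by 1.95 ± 0.15 and NACA2 fell by 1.94 ± 0.24; both have near-identical paralogs. The probe annotated to MIR574 fell by 2.10 ± 0.36 and was detected on 1 of 3 histamine arrays.

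In all, 2224 of 10406 genes changed (21.4%), 967 higher and 1257 lower. Of these, 410 changed at least 2-fold, 283 higher and 127 lower. The groups did not overlap for 37.4% of the genes tested, against the 10% that chance gives a single gene for 3 against 3. Genes vary together across arrays, so the share in 1 split can lie far from 10%, and this contrast does not test chance. Median scaling lines up the median of all probes, which lies below detection on every array, and so background levels rather than expressed genes. With arrays scaled to their medians in place of quantile normalization, the median log2 difference of all genes moved from -0.08 to -0.26. The split then became 456 higher and 1816 lower, or 20.1% higher against 43.5%. At least 2-fold, 177 were higher and 224 lower with that scaling. The count at least 2-fold was 107 without background correction, 70 in the processed value table and 210 with an offset of 50. Leaving out control replicate 1 gave 1455 changed genes (764 lower), and leaving out control replicate 2 gave 1218 (623 higher and 595 lower). Genes called lower numbered 819 without histamine replicate 1 and 815 without histamine replicate 3.

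**Figure D1:**
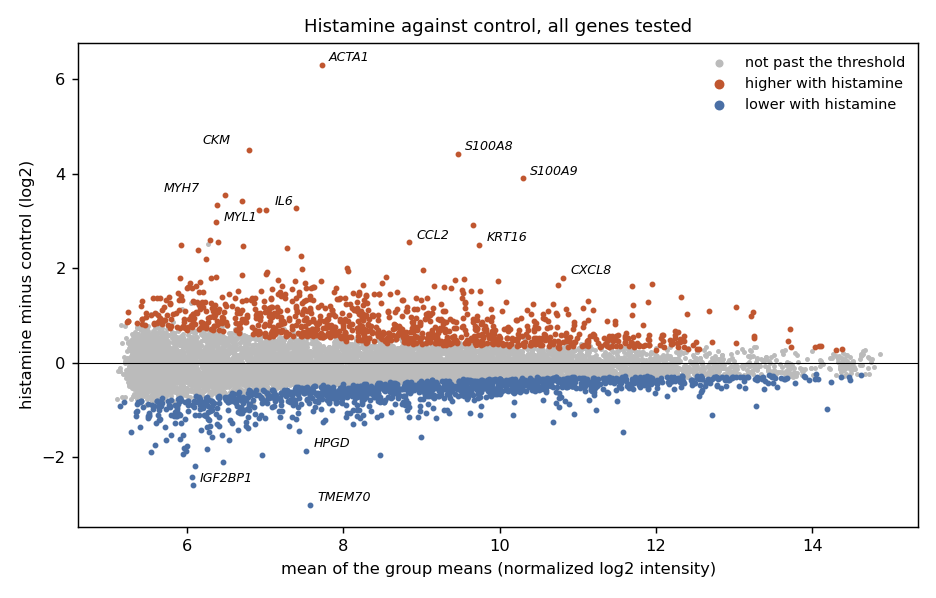
Each point is 1 of the 10406 genes tested, with the mean of the group means (normalized log2 intensity) on the horizontal axis and the fitted histamine minus control log2 difference on the vertical axis; orange marks the 967 genes called higher and blue the 1257 called lower. Differences of genes below background in 1 group, such as ACTA1, CKM and IGF2BP1, are fitted values at the floor of that group, and the split of higher and lower calls was 456 to 1816 with median scaling.

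Skeletal muscle transcripts were among the largest increases and came mainly from histamine replicate 1. ACTA1, skeletal muscle actin, was at least 44.5-fold higher with histamine, and CKM, muscle creatine kinase, at least 12.5-fold (adjusted p = 1.83e-05 and 0.00120). MYH7, a slow myosin heavy chain, was at least 7.27-fold higher and MYL1, a myosin light chain, at least 6.29-fold (adjusted p = 0.00468 and 0.00819). All were below background on every control array. The normalized log2 intensity of ACTA1 was 13.9 on histamine replicate 1, 9.51 on replicate 2 and 9.19 on replicate 3. That of CKM was 12.5, 7.53 and 7.11, that of MYH7 11.5, 6.29 and 7.03, and that of MYL1 11.4, 6.21 and 6.56. Without histamine replicate 1 the genes ACTA1, CKM, MYH7 and MYL1 kept their calls, with bounds of at least 15.5-fold, 3.79-fold, 2.39-fold and 1.98-fold. Without histamine replicate 2 the bounds were 71.4-fold, 21.2-fold, 14.4-fold and 11.9-fold, and without replicate 3 they were 79.8-fold, 24.5-fold, 11.2-fold and 10.6-fold. Of the 31 skeletal muscle genes on the array, 29 were at least 2-fold above the control mean on histamine replicate 1 and 7 on each of replicates 2 and 3. A limma fit that gives outlying variances less weight ended the calls of ACTA1, CKM, MYH7 and MYL1, and a fit without the intensity trend ended those of MYH7 and MYL1. Without histamine replicate 1, 1604 genes changed (785 higher and 819 lower), 415 of them at least 2-fold.

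Most measured antimicrobial and stress genes of the keratinocyte rose. Of the 12 measured members of the stress keratin and antimicrobial peptide list, 10 rose, none fell and 2, DEFB1 and KRT6C, did not pass the test (10, 0 and 2 adjusted over the list alone). The list has 22 members, so this covers only a part of it. Of its keratins KRT16 alone rose, by 2.49 with 0.79 on its other probe. CAMP, DEFB4A, IL36G and S100A12, among those not measured, were detected on no array. LTF was detected on 1 control array, DEFB103A on 1 histamine array and RNASE7 on 1 array of each group. The median log2 difference of the list was 2.06, or 2.05 with S100A7 at its bound. S100A7, the antimicrobial protein psoriasin, was below background on every control array and at least 5.54-fold higher with histamine. SERPINB4 rose 9.60-fold; SERPINB3 and SERPINB4 are near-identical, so their probes can read each other's transcripts. The list shifted upward (camera adjusted p = 1.26e-17, and adjusted p = 0.07 with an estimated correlation). Inflammatory cytokines and NF-kB targets also shifted upward (camera adjusted p = 1.58e-11, and adjusted p = 0.07 with an estimated correlation). Of their 17 measured members, 10 rose, none fell and 7 did not pass (11, 0 and 6 adjusted over the list alone). This cytokine list has 29 members, and TNF, CXCL2, CSF3, IL24 and IL33, among those not measured, were detected on no array. CXCL5 and IL20 were detected on 1 control array each, and CXCL3 and RELB on 1 array of each group. TSLP, left out by the detection filter, was detected on 2 of 3 control arrays and on no histamine array. CCL2, which attracts monocytes, rose 5.83-fold (2.54 ± 0.19). CXCL8, which attracts neutrophils, rose 3.47-fold (1.80 ± 0.11), with 1.90 on its other probe. CCL20, which attracts CCR6-bearing lymphocytes, was below background on every control array and at least 2.66-fold higher with histamine. S100A7, CCL20 and IL6, the last detected on 1 control array, passed the detection filter through the histamine arrays. That can build an upward shift into the tested members of both lists. For the changed genes of these lists, control replicate 3 lay at a median of 0.05 and 0.02 of the way from the mean of control replicates 1 and 2 to the histamine mean. Histamine replicate 1, which held the muscle transcripts, had a median log2 excess of 0.00464 over replicates 2 and 3 for the 34 genes that rose in the antimicrobial, cytokine and interferon lists.

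**Figure D2:**
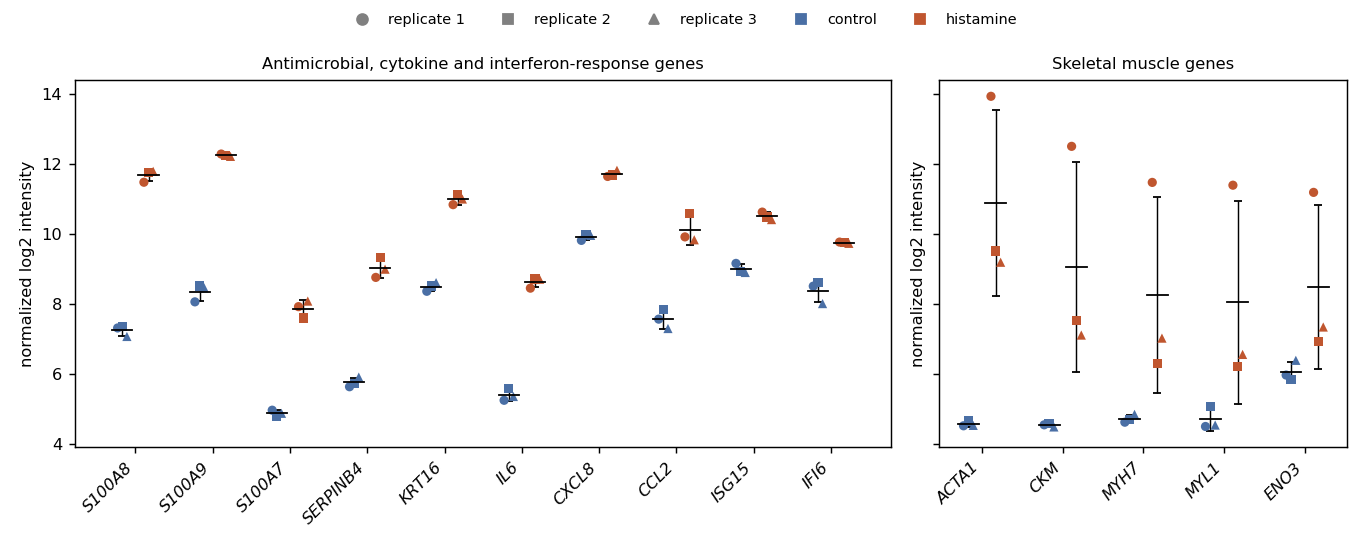
Normalized log2 intensity of 10 antimicrobial, cytokine and interferon-response genes (left) and 5 skeletal muscle genes (right) on each of the 6 arrays, with shapes for replicates, blue for control, orange for histamine, bars for group means and whiskers for SD. The 3 histamine values of the genes on the left lie close together, while ACTA1 reached 13.9 on histamine replicate 1 against 9.51 and 9.19 on replicates 2 and 3.

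Genes of the type I interferon response rose in 14 of 23 measured members, none fell and 9 did not pass the test (15, 0 and 8 adjusted over the list alone). ISG15, a ubiquitin-like modifier that interferon induces, rose 2.85-fold (1.51 ± 0.12; adjusted p = 2.76e-07). IFI6 rose by 1.37 ± 0.15, with 0.49 on its other probe, ISG20, an exonuclease, rose by 1.34 ± 0.17, and OAS2, an oligoadenylate synthetase, by 1.12 ± 0.23. The list shifted upward (camera adjusted p = 1.2e-10, and adjusted p = 0.16 with an estimated correlation), and HERC5, IFI44, IRF9, OAS1 and XAF1, which also rose, lost their calls with median scaling; the other OAS1 probes gave 0.55 and -0.01. Antigen presentation genes shifted upward as a list (camera adjusted p = 0.00366, and adjusted p = 0.323 with an estimated correlation). Of 13 members 2 rose, 1 fell and 10 did not pass (3, 1 and 9 adjusted over the list alone). HLA-F (1.94 ± 0.17, with 0.77 on its other probe) and HLA-B (0.78 ± 0.14) rose; these are class I molecules whose probes can read related HLA transcripts. TAP2, a peptide transporter, fell by 0.47 ± 0.15, with 0.07 on its other probe. The TAP2 call was lost with no filter on dim probes, with the mean of its probes, without the intensity trend, with the replicate number as a block, and without any 1 array except control replicate 1. Control replicate 3 lay at a median position of -0.25 for the changed interferon genes and 0.22 for the antigen presentation genes.

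Terminal differentiation and cornified envelope genes shifted upward (camera adjusted p = 0.0138, and adjusted p = 0.189 with an estimated correlation). Of 19 measured members 9 rose, 2 fell and 8 did not pass the test (9, 4 and 6 adjusted over the list alone). The list has 41 members, so the shift covers only a part of it. LORICRIN, FLG2, KRT2, CDSN, DSG1 and DSC1, among those not measured, were detected on no array. KRT1 was detected on 2 of 3 control arrays, CASP14 and OVOL1 on 1 each, and none of them on a histamine array. LCE1B and TGM5 were detected on 1 histamine array each and on no control array. SPRR2A and SPRR2D, small proline-rich precursors of the cornified envelope, rose by 1.51 ± 0.23 and 1.02 ± 0.25; SPRR2D was detected on 2 of 3 control arrays. GRHL3, a transcription factor of the epidermal barrier, rose by 1.46 ± 0.23, with 0.35 on its other probe. SCEL (sciellin), also an envelope precursor, fell by 1.16 ± 0.20, with -0.26 on its other probe, and CSTA, a cystatin, fell by 0.56 ± 0.19. CSTA, and the list members elsewhere that are named beyond the 4 with the largest difference, were chosen after their values were seen. The differentiation list was not called with no filter on dim probes or with a stricter filter. CALML5, DMKN, FLG and TGM1, which also rose, lost their calls with median scaling, as did SPRR2D with no filter on dim probes. KRT14, the basal layer keratin, rose by 0.53 ± 0.10, and ITGA6, a hemidesmosome integrin, rose by 0.69 ± 0.18. ITGA6 gave 0.25 on its other probe. Its call was lost with median scaling, with the mean of its probes, without the intensity trend, and without control replicate 1 or 2 or histamine replicate 3. Of the 12 measured basal keratinocyte genes, KRT14 and ITGA6 were the 2 that rose, none fell and 10 did not pass, with the same counts adjusted over the list alone; with median scaling 1 rose (KRT14) and 2 fell (ITGB4 and LAMB3). The basal list had a median of -0.001, a mean of 0.08 and an upward test (camera adjusted p = 0.28).

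PERP, a desmosome protein that p53 induces, rose by 1.16 ± 0.15 in the tight junction and desmosome list, and CLDN1 rose by 0.38 and lost its call with median scaling. The desmosome genes DSG3 (-0.88 ± 0.13), PKP3 (-0.49 ± 0.16) and DSC3 (-0.44 ± 0.11, with 0.31 on its other probe) fell. The calls of PKP3 and DSC3 were lost without the intensity trend and without control replicate 2 or histamine replicate 1, that of PKP3 also with no filter on dim probes and without control replicate 3 or histamine replicate 2, and that of DSC3 also on the mean of its probes. Of the 18 measured members, 13 did not pass; adjusted over the list alone, 2 rose, 5 fell and 11 did not pass. The downward shift of the junction list did not pass (camera adjusted p = 0.368). The median position of control replicate 3 was 0.13 for the changed differentiation genes, 0.52 for the basal list and 0.26 for the junction list.

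DNA replication genes were lower with histamine (camera adjusted p = 0.0138, and adjusted p = 0.417 with an estimated correlation). Of 25 measured members 10 fell, 2 rose and 13 did not pass the test (11, 2 and 12 adjusted over the list alone). MCM4, a subunit of the replicative helicase, fell by 0.62 ± 0.11, with -0.52 on its other probe. ORC1, of the origin recognition complex, fell by 0.72 ± 0.17, and CDC6, which loads the helicase, fell by 0.80 ± 0.24. The CDC6 call was lost with no filter on dim probes and without control replicate 1 or 2 or histamine replicate 2 or 3. E2F1, a transcription factor of S phase genes, rose by 1.10 ± 0.24, and PCNA, the polymerase clamp, rose by 0.53 ± 0.10, with -0.30 on its other probe, and lost its call with median scaling. Mitosis genes had 7 of 26 fallen, 2 risen and 17 not past the test, with the same counts adjusted over the list alone. Their downward shift did not pass by camera (adjusted p = 0.0826) but did by fry (adjusted p = 0.0455), and by camera with median scaling. TOP2A, a topoisomerase, fell by 0.70 ± 0.13, and TPX2, a spindle assembly factor, fell by 0.68 ± 0.12. KIF11, a mitotic kinesin, fell by 0.67 ± 0.13, with 0.32 on its other probe and no call on their mean. BUB1B, a checkpoint kinase, rose by 0.80 ± 0.22, a call lost without the intensity trend and without control replicate 1 or 2 or histamine replicate 3. CDK1 rose by 0.34, with 1.03 on its other probe, and lost its call with median scaling. Control replicate 3 lay at a median position of 0.25 for the changed replication genes and 0.45 for the mitosis genes.

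Genes of EGFR signalling moved both ways. The phosphatase DUSP5 rose by 1.25 ± 0.18, and the signalling inhibitor SPRY2 and the EGFR ligand TGFA each rose by 0.93 ± 0.16, TGFA with 0.47 on its other probe. The immediate early genes EGR1 (-0.78 ± 0.13) and FOS (-0.71) and the receptor EGFR itself (-0.61, with -0.80 on its other probe) fell. DUSP6, ETV5 and HBEGF also rose but lost their calls with median scaling; DUSP6 and ETV5 gave -0.04 and 0.33 on their other probes. Of 17 measured members of the list 6 rose, 3 fell and 8 did not pass (7, 3 and 7 adjusted over the list alone; camera adjusted p = 0.0585, upward). The list median was 0.11, and -0.08 with median scaling. PLAU, the urokinase plasminogen activator, rose 2.37-fold (1.25 ± 0.12; adjusted p = 2.71e-06), and MMP10, stromelysin 2, fell by 1.28 ± 0.27, a call lost without the intensity trend. CCN2, MMP1, TNC and THBS1 also rose but lost their calls with median scaling, CCN2 also without any 1 array except histamine replicate 2 and MMP1 without control replicate 1 or 2 or histamine replicate 2 or 3. CCN2 and MMP1 also lost them with no filter on dim probes and without the intensity trend. These were the 5 risen and 1 fallen of 17 matrix, protease and TGF-beta target genes, with 11 not past the test (7, 1 and 9 adjusted over the list alone). The upward shift of the matrix list did not pass by camera (adjusted p = 0.0548) but did by fry (adjusted p = 0.0455). Control replicate 3 lay at a median position of 0.23 for the changed EGFR genes and 0.36 for the matrix genes.

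Hypoxia and glycolysis genes were lower (camera adjusted p = 0.00643, and adjusted p = 0.406 with an estimated correlation). Of 18 measured members 9 fell, none rose and 9 did not pass the test (12, 1 and 5 adjusted over the list alone). BNIP3, a mitophagy receptor that hypoxia induces, fell by 1.10 ± 0.23, and ADM, adrenomedullin, fell by 0.62 ± 0.12. ANKRD37 fell by 0.74 ± 0.25 and NDRG1 fell by 0.49 ± 0.16, with groups that overlap and control replicate 3 at positions 0.947 and 0.876. Both calls were lost with no filter on dim probes, without the intensity trend, and without control replicate 1 or 2 or histamine replicate 1 or 3. That of ANKRD37 was also lost with the replicate block and without histamine replicate 2. The BNIP3 call was lost without the intensity trend and with robust moderation. The hypoxia list was not called by fry or without the intensity trend. Metallothionein genes, which encode metal-binding proteins, shifted downward (camera adjusted p = 0.0297, and adjusted p = 0.34 with an estimated correlation). MT1E fell by 0.91 ± 0.13, MT2A fell by 0.51 ± 0.11, MT1X fell by 0.49 ± 0.11 and the zinc exporter SLC30A1 fell by 0.72 ± 0.21, with -0.57 on its other probe. MT1F, MT1G and MT1H did not pass, so that 4 of 7 fell, none rose and 3 did not pass over all genes and adjusted over the list alone. The metallothionein list and the calls of MT2A, MT1X and SLC30A1 were lost without the intensity trend, and that of SLC30A1 also with no filter on dim probes and without control replicate 2 or histamine replicate 2. MT1 probes can read each other's transcripts. Genes of the mitochondrial respiratory chain had 6 of 20 fallen, 2 risen and 12 not past the test (7, 2 and 11 adjusted over the list alone). Their downward shift did not pass by camera (adjusted p = 0.0548) but did by fry (adjusted p = 0.0014). NDUFS1, of complex I, fell by 0.91 ± 0.24, a call lost with no filter on dim probes. CYC1 fell by 0.37 ± 0.11. Its call was lost with no filter, without the intensity trend, and without control replicate 1 or 2 or histamine replicate 1 or 3. ATP5F1C (0.48 ± 0.13), of the ATP synthase, and UQCRC2 (0.39 ± 0.13), of complex III, rose and lost their calls with median scaling, with no filter and without the intensity trend. They also lost them without control replicate 1 or 2 or histamine replicate 2, and UQCRC2 without histamine replicate 1 or 3 as well. The median position of control replicate 3 was 0.38 for the changed hypoxia genes, 0.31 for the metallothionein list and 0.50 for the respiratory chain.

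Heat shock protein genes shifted upward (camera adjusted p = 0.00362, and adjusted p = 0.192 with an estimated correlation). Of 13 measured members 5 rose, none fell and 8 did not pass the test, with the same counts adjusted over the list alone. HSPA1A, a stress-induced HSP70, rose 3.09-fold (1.63 ± 0.18), and the small heat shock protein HSPB1 rose by 0.47 ± 0.10. The cochaperone BAG3 rose by 0.37 ± 0.10 and HSPA1B, a near-identical copy of HSPA1A, by 0.29. BAG3 also lost its call without control replicate 2 or histamine replicate 2, and BAG3 and HSPB1 without the intensity trend. BAG3 and HSPA1B lost their calls with median scaling, under which the list median of 0.08 became -0.001. HSPA4 rose by 1.62 ± 0.18 on its brightest probe, with -0.40 on its other probe. ATF3, a stress-induced transcription factor, rose 3.40-fold (1.77 ± 0.17) in the list of unfolded protein and amino acid stress. SDF2L1 also rose but lost its call with median scaling, without the intensity trend and without any 1 array except control replicate 3, and PSAT1, SLC3A2, PHGDH, SLC7A5 and XBP1 fell, with 0.02 on the other probe of XBP1. SLC3A2 lost its call with no filter on dim probes and without any 1 array except control replicate 3 and histamine replicate 3, and SLC3A2 and PSAT1 without the intensity trend. Of the 16 members 9 did not pass; adjusted over the list alone, 3 rose, 5 fell and 8 did not pass. This list had a median of -0.13, a mean of 0.04 and a downward test (camera adjusted p = 0.889). HMOX1, heme oxygenase 1, rose by 1.50 ± 0.25 and was detected on 2 of 3 control arrays. ME1, malic enzyme, rose by 0.87 ± 0.18, and AKR1C3 rose by 0.40 ± 0.12 and lost its call with median scaling, without the intensity trend and without control replicate 1 or 2 or histamine replicate 2 or 3. These were the 3 of 13 NRF2 targets that rose, none fell and 10 did not pass (3, 2 and 8 adjusted over the list alone; camera adjusted p = 0.143). With median scaling 2 of them rose (HMOX1 and ME1) and 2 fell (AKR1C2 and TALDO1). Control replicate 3 lay at a median position of 0.45 for the changed heat shock genes, -0.18 for the unfolded protein list and 0.33 for NRF2 targets.

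CYP51A1, a demethylase of sterol synthesis, rose 3.37-fold (1.75 ± 0.19), IDI1 rose by 1.09 ± 0.18 and FDPS, farnesyl diphosphate synthase, by 0.90 ± 0.17. MSMO1, a sterol oxidase, rose by 0.87 ± 0.12, with 0.46 and -0.11 on its other probes. These were the 4 of 18 cholesterol synthesis genes that rose; 1, PMVK, fell and 13 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0548, upward). The list median was 0.01, and -0.20 with median scaling. RPL5, RPL13, RPL35 and RPLP2 were the 4 of 24 cytosolic ribosomal protein genes that rose. RPL30 was the 1 that fell and 19 did not pass, with the same counts adjusted over the list alone. RPL5 rose by 0.56 ± 0.11, and the other 4 lost their calls with median scaling. RPL13 and RPL35 also lost them without the intensity trend and without control replicate 2 or histamine replicate 2, RPL13 on the mean of its probes, the other of which gave -0.17, and RPL35 with no filter on dim probes. The ribosomal list had a median of -0.02, a mean of 0.04 and an upward test that did not pass (camera adjusted p = 0.28) but did with median scaling. Control replicate 3 lay at a median position of 0.17 for the changed cholesterol genes and 0.45 for the ribosomal genes.

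**Figure D3:**
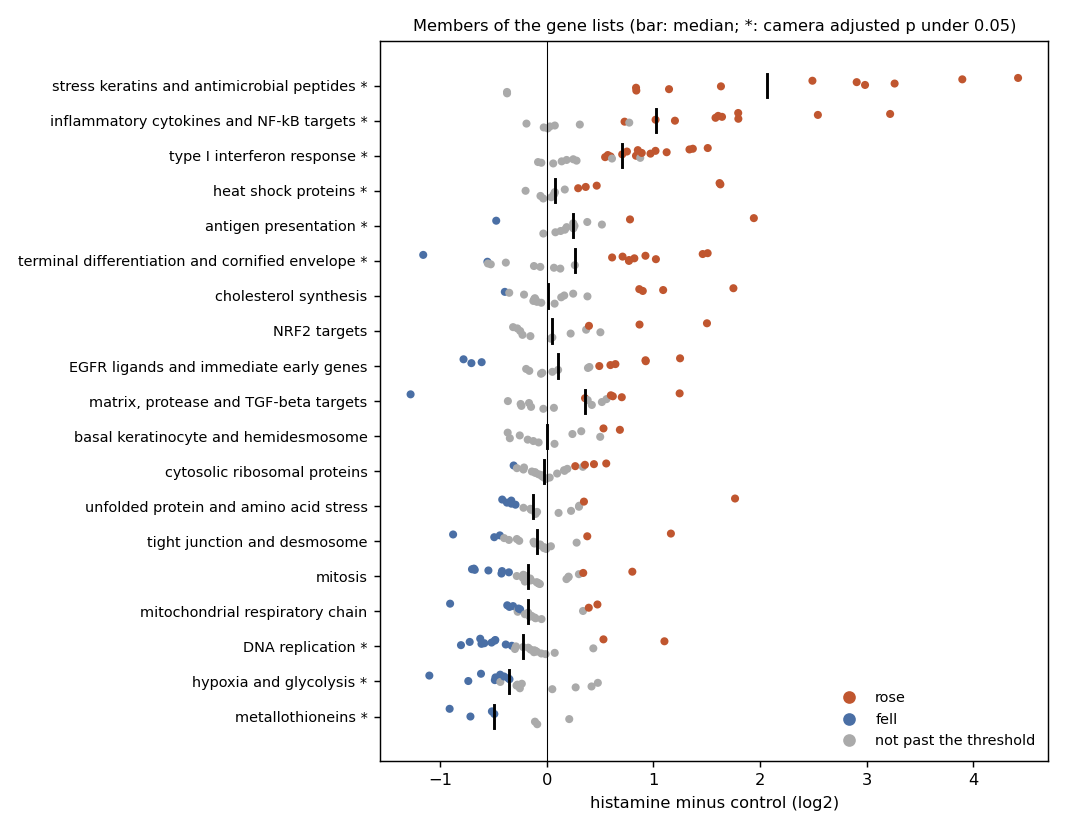
Histamine minus control log2 difference of each measured member of the 19 lists tested, with orange for members that rose, blue for members that fell, grey for the rest, a bar at the median and an asterisk at the 9 lists with a camera adjusted p under 0.05. With median scaling the medians of the EGFR, cholesterol, heat shock and NRF2 lists turn from above 0 to below, and that of the ribosomal list from below 0 to above.

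Of 24 lists, 19 had enough measured members for the test, and 9 shifted, 6 upward and 3 downward. None of the 9 calls held with an estimated correlation. For the differentiation list that estimate was -0.0453, below the preset 0.01, while its unadjusted camera p rose from 0.00572 to 0.0399. A higher correlation thus does not account for the loss of that list. Fry, which asks whether the genes of a list move one way on balance, called 11 lists, 8 of them among the 9; the other 3 are mitosis, matrix and respiratory chain. With median scaling, members of other lists that passed only there were, as decreases, CNFN, PPL, DEFB1, CTNNB1, JUP, AURKA, UHRF1, SC5D, ALDOC, PFKFB3, NDUFB3 and UQCRC1, and, as increases, IFI27 and RPLP1; the decreases of ATP5F1A and ATP5F1B did not pass there.

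HRH1, the H1 histamine receptor, was detected on all 6 arrays with a log2 difference of -0.03 ± 0.26 (adjusted p = 0.954). AOC1, the diamine oxidase that degrades histamine, gave -0.61 ± 0.33 (adjusted p = 0.212) and was detected on 2 of 3 histamine arrays. Neither of these 2 measured members of the histamine receptor and metabolism list passed the test, also adjusted over the list alone, but AOC1 passed it as a decrease with median scaling. HRH2, HRH3 and HRH4, the other histamine receptors, HDC, which makes histamine, and MAOB were detected on no array, and HNMT, which methylates histamine, on 1 histamine array. Markers of other skin cell types were mostly below background. FBLN1, the 1 measured fibroblast marker, gave 0.14 ± 0.15, and MITF, the 1 measured melanocyte marker, gave 0.16 ± 0.28 and was detected on 2 of 3 control arrays. Of 2 measured immune cell markers CD14 gave 0.16 ± 0.15, while CD68, a lysosomal protein that macrophages share with other cells, rose by 1.26 ± 0.19 on its brightest probe. The other CD68 probes gave 0.16 and -0.11, and the call was lost on the mean of the probes. These marker lists gave the same calls adjusted over the list alone, and no endothelial marker was measured.

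Control replicate 3 lay nearer to the histamine arrays than the other controls did. Over all 2224 changed genes its median position was 0.23, where 0 is the mean of control replicates 1 and 2 and 1 is the histamine mean. Per the labels, the sample names of the control arrays belong to 1 numbered series and those of the histamine arrays to another, so a processing batch that follows these series cannot be told apart from histamine.

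**Figure D4:**
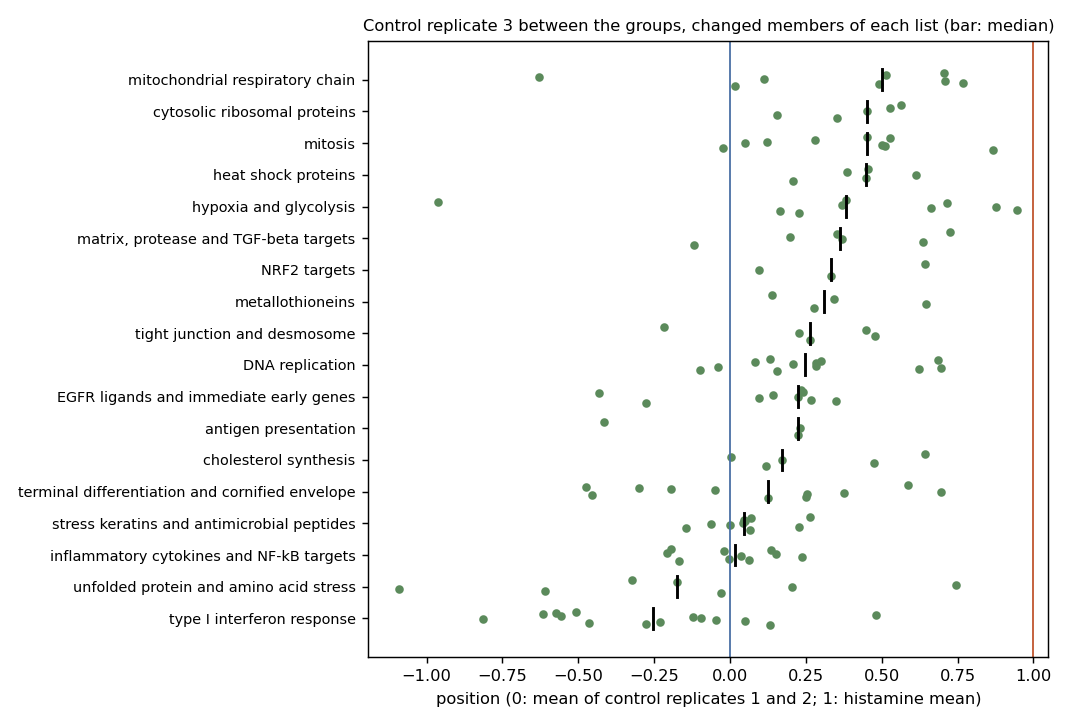
Position of control replicate 3 for each changed gene of the lists with at least 3 such genes, on a scale with 0 (blue line) at the mean of control replicates 1 and 2 and 1 (orange line) at the histamine mean; bars mark list medians. Medians ran from -0.25 for interferon genes to 0.50 for the respiratory chain.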

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

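All tests reported here were chosen only after the results they address were seen.

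Among probes left out by the detection filter, 31 were above 8 on the log2 scale on histamine replicate 1, against 0, 1 and 0 on the control arrays and 0 and 0 on the other histamine arrays; these probes lie outside the comparison of genes. They stand for 25 different genes with a symbol, 14 of them in the skeletal muscle list. Of 10 muscle genes in the comparison 9 rose. The excess over the control mean on histamine replicates 1, 2 and 3 was 9.35, 4.94 and 4.62 for ACTA1, while TNNT1, detected on all 3 control arrays, had 1.29, 1.11 and 0.23. Of the 31 muscle genes on the array, 3 were detected on any control array, and 29 (93.5%) were at least 2-fold above the control mean on histamine replicate 1.

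The tables argue against induction by histamine as the cause of that level. Histamine replicate 1 exceeded replicates 2 and 3 by a median of 3.83 on the log2 scale over 31 muscle genes. The other 402 genes changed at least 2-fold had a median excess of -0.0267 (central 95% from -0.81 to 0.568). The sets are unlike: the 402 genes passed a test that favours replicates that agree, which narrows their range, while 10 of the 31 muscle genes were tested. RNA of skeletal muscle in the sample of histamine replicate 1 is a candidate source: ACTA1 reached 13.9 there and CKM 12.5, and the 3 hemoglobin genes HBA1, HBA2 and HBB were at least 2-fold above control, while 0 of 7 heart, 0 of 12 liver, 0 of 6 adipocyte and 0 of 10 tissue stroma genes were. For the traces on replicates 2 and 3, carry-over of such RNA and a small induction by histamine cannot be told apart, because the excess there follows that on replicate 1 across 31 muscle genes (rank correlation across genes 0.811) and both would be absent from the controls. Muscle RNA does not account for the rise of antimicrobial, cytokine and interferon genes. The 34 genes that rose in those lists had a median excess on histamine replicate 1 of 0.00464 (from -0.592 to 0.289).

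Control replicate 3 lies between the other controls and the histamine arrays, at a median position of 0.229 over all changed genes. RNA of a histamine sample in control replicate 3 would move risen genes with a like size of change alike. The 34 risen antimicrobial, cytokine and interferon genes lay at -0.0106 (quartiles -0.203 and 0.0657) and the other 933 risen genes at 0.301. Of 10000 random sets matched for size of change (median 0.231, central 95% from 0.0865 to 0.315), 5 were as low, which argues against such RNA. The random sets drew genes singly, while genes of these lists may move together, so 5 of 10000 is not a p-value. A difference in handling or culture that control replicate 3 shares with the histamine samples stays open: its difference from 1 control correlated with the histamine mean minus the other control at 0.427 and 0.478 across changed genes, and the labels give no handling record. Such a difference may account for part of the changes in respiratory chain, mitosis, heat shock and ribosomal genes, whose positions were 0.45 to 0.50, more than for interferon genes (-0.254).

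Probes of the same gene often disagreed. Of 681 changed genes with a second kept probe, that probe had the same sign for 477 (70%), and at an unadjusted p under 0.05 there were 250 with the same sign and 80 with the opposite. Dim second probes do not account for this as a whole, since among second probes above 10 on the log2 scale 73 of 92 (79.3%) had the same sign, against 82 of 129 (63.6%) at or under 6. For the 80 genes opposite at that p, single transcript forms, an array difference at single probes and probes that read other transcripts cannot be told apart. No probe coordinates were used, and as that p is unadjusted, chance can account for some of the 80. The rest of the 204 opposite second probes did not reach that p, so their sign is not settled. For changes of at least 1.5 on the log2 scale 21 of 22 genes had the same sign, and for the genes that rose in the antimicrobial, cytokine and interferon lists 9 of 9 did.

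Of the 4125 kept probes without a gene symbol, which no comparison of genes uses, 552 were higher with histamine and 436 lower. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. Every other split mixes control and histamine arrays, which adds the difference of the groups to the spread. Counts of changed genes near 0 are thus almost fixed in advance there, so their contrast with the real split does not test chance. The real split gave 2224 changed genes against 0 for the highest other split, and 410 at least 2-fold against 0, so that 1 split, the real one, reached each count. For lists it gave 9 against 11 for the highest other split, and 2 splits reached 9 or more. A processing batch cannot be told apart from histamine, because 0 of the 2 numbered series of sample names hold both groups.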

How the results depend on the processing

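Leaving out skeletal muscle and hemoglobin genes was chosen after seeing the data; it gave 2256 changed genes and 9 lists. The main counts were 2224 changed genes (967 higher, 1257 lower), 410 at least 2-fold (283 higher, 127 lower) and 9 lists. Of 88 named genes past the threshold, 54 kept their call under every alternative that measured them, and 0 reversed a call. Of all changed genes, 6 were called with the opposite sign on the mean of their probes. The cause of the shifts below was not tested, except where the construction gives it. Changed genes numbered 1477 (794 lower) with no filter, which tests more genes, 3916 (1969 higher, 1947 lower) with all kept probes tested singly, which counts probes, 1373 (638, 735) without the trend, and 1041 (547, 494) at an adjusted p under 0.01, by construction. Median scaling gave 456 higher. Counts at least 2-fold are compressed without background correction (107; 93 higher, 14 lower), in the processed table (70; 62, 8) and with the larger offset (210; 165, 45). They were 248 (51 lower) with the stricter filter, which drops dim genes, 1063 (694, 369) for single probes, and 177 higher and 224 lower with median scaling. Leaving out 1 array, which also removes degrees of freedom, gave 1218 to 2544 changed genes (1455 without control replicate 1, 1218 without control replicate 2), 623 to 1088 higher (623 without control replicate 2) and 595 to 1456 lower. Lower genes were 764 and 595 without control replicates 1 and 2, and 819 and 815 without histamine replicates 1 and 3. The ranges at least 2-fold were 336 to 516 (225 to 356 higher, 111 to 160 lower), and for lists 10 to 12. An estimated correlation called 0 lists. With no trend 7 lists were called (hypoxia and metallothioneins lost), and at an adjusted p under 0.01, 6 (differentiation, DNA replication and metallothioneins lost). The differentiation list was also lost with no filter and with the stricter filter, and no list call was lost when 1 array was left out. With the replicate block, 1903 genes changed, 411 at least 2-fold, and 10 lists shifted; the numbers do not pair the samples, since samples of the same number correlated at -0.0316, -0.0289 and -0.0457 after removal of the group means. Genes below background in 1 group limit the precision: their size is a bound.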

Other observations

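The genes named here, and all tests reported here, were chosen only after the results were seen.

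CYP24A1, which degrades active vitamin D, was below background on every control array and at least 4.56-fold higher with histamine (adjusted p = 1.09e-06). CYP27B1, which makes active vitamin D, rose by 1.47 ± 0.17 on the log2 scale, and the vitamin D receptor VDR gave -0.58 (adjusted p = 0.0509). PTGS2, a prostaglandin synthase, rose by 1.02 ± 0.15, with 0.87 on its other probe, and HPGD, which degrades prostaglandins, fell by 1.87 ± 0.18; no list of prostaglandin genes was tested. CYP1A1, a target of the aryl hydrocarbon receptor, rose by 1.49 ± 0.18. UBD, an inflammatory ubiquitin-like modifier detected on 1 of 3 control arrays, rose by 2.56 ± 0.27, and the tissue plasminogen activator PLAT rose by 1.37 ± 0.22.

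SAA1 and CFB (1.92 ± 0.25) led to the hypothesis that acute phase and complement genes rise as a group. Of 23 members on the array the detection filter left 9 to test, and 4 rose. Among them were CD55 (1.51 ± 0.24), a complement regulator, and F3 (0.62 ± 0.16, with 1.28 on its other probe), tissue factor. Without SAA1, SAA2 and CFB, 7 measured members had a median log2 difference of 0.62 and shifted upward (camera p = 0.00334; p = 0.0837 with an estimated correlation), with 2 risen. C1R and C1S were detected on 3 histamine and 0 control arrays, and SERPINA3 on 3 and 1. They thus passed the filter through the histamine arrays. That can build an upward shift into the tested members, so a shift beyond the genes that prompted it cannot be concluded.

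Fewer DNA replication transcripts and more transcripts of the measured differentiation genes could come from denser cultures in the histamine samples. Denser cultures would lower the targets of YAP and TEAD. Of 19 tested targets 6 rose (CCN2, ANKRD1, F3, IGFBP3, GADD45A and NT5E) and 2 fell (ASAP1 and PTPN14), with a median of 0.04 and an upward test that did not pass (camera p = 0.0912; p = 0.291 with an estimated correlation; p = 0.185 without ANKRD1). The other ASAP1 probes gave -0.71 and 0.29, and the other PTPN14 probe gave 0.23. ANKRD1 is also a striated muscle gene, and its excess over the control mean was 4.01 on histamine replicate 1 against 0.89 and 1.85 on replicates 2 and 3. Density thus stays open: cytokines can also raise members of this list, and no cell counts were used here.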
